A study of Mus musculus with 25 samples.

How the data were processed

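Genomic DNA from the contralateral mammary fat pads of 25 mice was analysed by RRBS; per the labels it was cut with MspI and fragments of 40 to 170 bp were amplified. The authors processed the reads with Bismark against mm10 and gave no versions, filters or coverage minimum. The authors deposited a table with, per CpG and library, the methylation level as a fraction of reads (0 to 1, missing where no value is given). The deposited table also holds an average coverage signal per CpG, in reads over 21 libraries, group methylation values in percent, a difference between obese and control in percentage points (another unit, as the file headers name it) and a p-value and q-value for that contrast. The coverage multiplied by 21 was a whole number at 100% of the CpGs, within a tolerance of 1e-06. Read counts and depths per library were not used here, as the table has none, so the precision of single values is unknown and no binomial intervals were computed. Each library was matched to its mouse by the library name in the sample title, and groups were taken from the labels.

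Levels are printed in percent. The comparisons on 25 libraries, the thresholds, the gene lists and most of the other settings tried were set before the data were examined. What the table did not allow was adapted afterwards, as said at each step. Of the 283974 CpGs, 65 on other sequences than the chromosomes were left out. A minimum of 10 reads per CpG and mouse had been planned and was applied to the average coverage instead, the only depth in the table. CpGs also needed a value in at least 3 mice of every group with that many mice, which left 76974 CpGs on 25 libraries and 129215 on 21. A model of read counts had been planned, but the table gives fractions, so the planned fallback was used: limma on the level with 1 term per group, every mouse weighted alike, variance moderated across CpGs (squeezeVar), trend and robust options off, two-sided, Benjamini-Hochberg adjustment over CpGs, and a call at an adjusted p under 0.05. Groups pooled for the calorie-restricted comparisons formed 1 term. The file gives no transcription start sites, so in place of the planned window around the start a promoter was made of the CpGs the authors annotate to the features upstream of the start, the 5'UTR and the 1st exon of a gene, with at least 3 CpGs; 1st exon CpGs make up most of these. A promoter level is the mean of its CpG means plus the mean deviation of the mouse over the CpGs it has, given where it has at least 0.5 of them. Genes that share CpGs share values. All such CpGs of a gene were pooled, also where they lie far apart, as at Hoxa3, Gnas and Dnmt3a.

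The promoters named per comparison are the 10 higher and 10 lower ones of largest difference among those called, or, with fewer than 10 calls, those of smallest p, and per list the members of smallest p; CpGs are those of largest difference. Of these the text gives a part. Mean methylation is the unweighted mean over CpGs measured in every library, compared by exact permutation tests of the difference of means, two-sided. Their smallest possible p is 0.0286 for 4 against 4 or 3 against 4 mice, 0.0179 for 3 against 5, 0.00794 for 4 against 5 or 5 against 5, and 0.000549 for 12 against 4. The score between Control and Obese is a projection over the 1000 CpGs of smallest p, with Control and Obese mice scored with themselves left out. The correlation of the obese change with the diet change was set beside simulated data with no effect and beside splits of the shared mice. The 20 gene lists were tested with limma cameraPR at a preset correlation of 0.01, camera with an estimated correlation and fry; lists with fewer than 3 measured promoters were not tested. The fry test asks whether a list moves one way, without regard to other genes.

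The comparisons of LFD, LFCR, MCR and ICR with Control on the 21 libraries outside the 4 that stand apart were added after the data were seen. Alternatives were a coverage minimum of 5 or 20 reads, a minimum difference of 10 points, at least 10 CpGs per promoter, other sizes and forms of the score, an estimated correlation and leaving out each mouse in turn. Added after the data were seen were leaving out the 4 libraries, an arcsine square root scale, promoters without the 1st exon and lists over all CpGs of a gene. A promoter window by distance from the start and the methylated share of all reads could not be run without start sites and counts. On simulated differences of 10, 20, 30 and 40 points at single CpGs, the same fit recovered 2%, 18%, 42% and 66% in Obese against Control and 0%, 8%, 30% and 56% in MCR against Control. The simulated levels took means and spread from the 21 libraries outside the 4, with 50 changed CpGs per size. The wide spread brought by the 4 libraries and the many called CpGs of the real data were thus absent. These rates therefore do not give the recovery of the real fits. Software was R 4.3.3, limma 3.58.1, the data.table package (1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.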

Results

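DNA methylation was measured in 25 mouse mammary fat pads by reduced representation bisulfite sequencing (RRBS), which reads short MspI fragments rich in CpG sites. Per the labels, C57BL/6N mice ate a control diet (Control, n = 5) or a 60% high-fat diet, and the obese mice then stayed obese (Obese, n = 4) or changed to 1 of 4 weight-loss diets. These were an unrestricted low-fat diet (LFD, n = 4), a low-fat diet with 30% calorie restriction (LFCR, n = 4), a Mediterranean-style diet with 30% calorie restriction (MCR, n = 3) and intermittent calorie restriction (ICR, n = 5). E0771 mammary cancer cells were injected into a fat pad of each mouse, and the DNA came from the uninjected pad of the opposite side. The sample titles also hold the word tumor. The deposited table lists 283974 CpG sites on mm10. It gives no read depth per library, so the depth behind each single value is unknown. Its average coverage per CpG, over 21 libraries, had a median of 29.3 reads, with 25th and 75th percentiles of 16.8 and 53.9. Each library had a value at 48.3% to 99.5% of the CpGs.

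The libraries of Obese mice 27, 28 and 40 and of LFD mouse 46 carried high methylation where all other libraries had almost none. At 24513 CpGs with a mean level under 5% in Control, these 4 libraries had mean levels of 49.6% to 50.1%, and the other 21 libraries had 1.10% to 1.85%. Obese mouse 22 was at 1.66%. The promoters of 18 housekeeping genes had a median level of 49.4% to 50.8% in the 4 libraries and of at most 0.769% in each of the other 21. For these promoters a single CpG was enough. The median gap between the 4 and the 21 libraries was 48.2 points at CpGs under 5%, 3.87 points at CpGs of 10% to 30% and 1.55 points at CpGs over 90%. In the authors' table, the group value for diet-induced obesity equals the level of Obese mouse 22 alone at 100% of the CpGs, and the average coverage is taken over 21 libraries. For these reasons each weight-loss diet was also compared with Control on the 21 other libraries, a set of comparisons chosen after the data were seen, and these come first below.

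**Figure D1:**
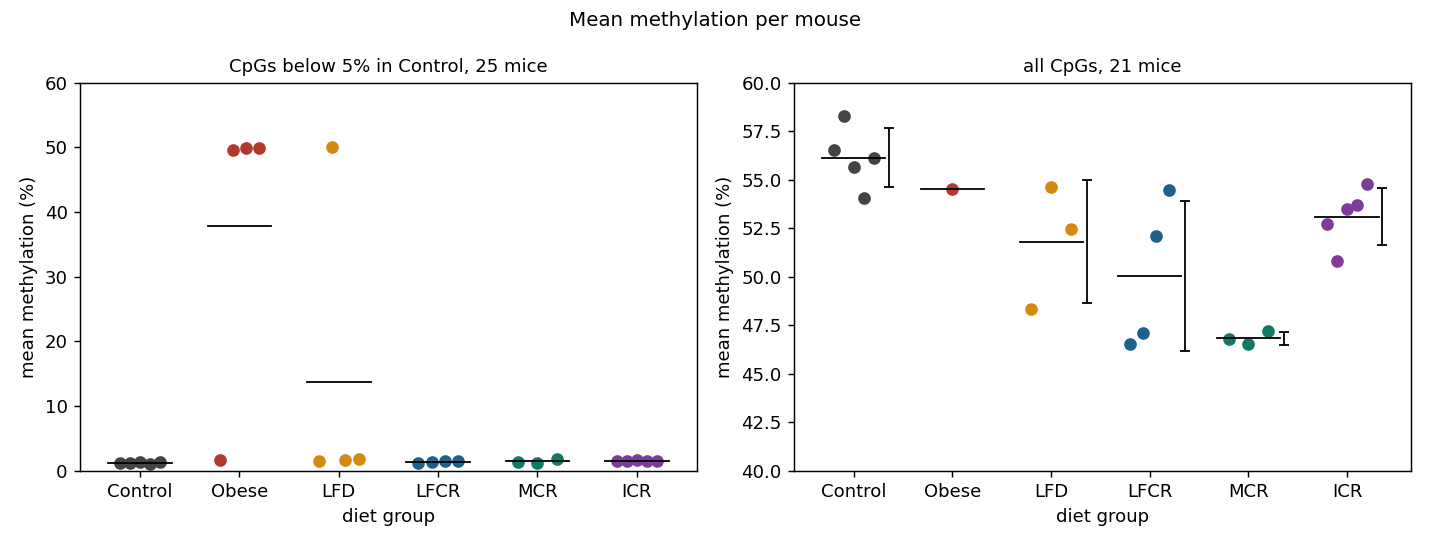
Mean methylation (percent) per mouse by diet group, with 1 point per mouse and a line at each group mean. On the left, CpGs under 5% in Control in all 25 mice, where 4 mice lie between 49.6% and 50.1%. On the right, all CpGs measured in the 21 other mice, with bars of 1 SD, where the 3 MCR mice have a mean of 46.8% and the Control mice 56.1%.

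Mean methylation was lower in each weight-loss group than in Control. The weight-loss mice had first eaten the high-fat diet and become obese, and the Control mice had not. These comparisons therefore cannot separate that earlier state from the weight-loss diet. Over 95331 CpGs measured in all 21 libraries it was 56.1% ± 1.52 (SD, n = 5) in Control, 53.1% ± 1.48 (SD, n = 5) in ICR, 51.8% ± 3.18 (SD, n = 3) in LFD, 50% ± 3.87 (SD, n = 4) in LFCR and 46.8% ± 0.343 (SD, n = 3) in MCR. Obese mouse 22 was at 54.5%. The difference from Control was -9.31 points in MCR (exact permutation test, two-sided, p = 0.0179, adjusted p = 0.0238 over 4 comparisons), with 3 of 3 mice below every Control mouse. For LFCR it was -6.10 points (exact permutation p = 0.0159, adjusted p = 0.0238), with 3 of 4 mice below every Control mouse. For LFD it was -4.33 points (exact permutation p = 0.0357, adjusted p = 0.0357; 2 of 3 mice), and for ICR -3.04 points (exact permutation p = 0.0159, adjusted p = 0.0238; 4 of 5 mice). In MCR the difference was -6.24 points over CpG islands, -8.58 over shores, -11.0 over shelves and -10.6 over open sea, the CpGs far from islands. Without Control mouse 1, 2, 5 or 13 every one of these 4 comparisons had an adjusted p of at least 0.0571. The same held for LFD without LFD mouse 42 (-2.60 points) or 48 (-4.67 points).

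The MCR fat pads had lower methylation than Control pads at many promoters and higher methylation at few. No pad was measured before the diets, so losses and gains here mean lower and higher than in Control. In MCR against Control, 1207 of 2792 promoters were lower and 119 higher at an adjusted p under 0.05 (limma). The largest gains were at Arhgap30, with 79.7% ± 3.64 (SD, n = 3) in MCR and 30.2% ± 14.0 (SD, n = 4) in Control, and at Dok3, an adaptor protein of immune receptors, with 78.1% ± 3.62 (SD, n = 3) and 30.7% ± 10.1 (SD, n = 5). Their differences were 49.5 points (SE 12.2, adjusted p = 0.00413) and 47.4 points (SE 8.50, adjusted p = 0.000895). F2rl3, a thrombin receptor of platelets, was higher by 43.1 points, Rps6ka1, a ribosomal S6 kinase, by 37.6, Lat, an adaptor of the T cell receptor, by 35.4, and Inpp5d, an inositol phosphatase of blood cells, by 34.6. Gm12977, whose promoter CpGs lie among those of Rps6ka1, Gm10392, Rhbdf2 and Atp2b2, a calcium pump, were higher by 29.2 to 41.0 points. The largest losses were at Cldn15, a claudin of tight junctions, with 17.3% ± 9.41 (SD, n = 3) in MCR and 74.6% ± 1.80 (SD, n = 3) in Control, and at Agap2, a GTPase-activating protein, with 10.5% ± 2.39 (SD, n = 3) and 57.9% ± 9.13 (SD, n = 5) over 62 CpGs. Their differences were -57.3 points (SE 8.70, adjusted p = 0.000823) and -47.5 points (SE 8.01, adjusted p = 0.000798). Nrip2 and Gm44596, which share their promoter CpGs, fell by 47.4 points, Cd37, a tetraspanin of leukocytes, by 46.3, Amotl2, an angiomotin-like protein, by 45.5, and Mxra8, a matrix remodelling protein, by 43.5. Gm11523, Gm15684 and Mxra8os fell by 43.9, 43.9 and 43.4 points. At each of these 20 promoters all 3 MCR mice lay beyond every Control mouse. They were chosen for large differences in these same mice, and some share CpGs, so this adds no further support. Inpp5d had 3 measured mice per group, and its call was lost without Control mouse 2 or 13 or MCR mouse 85 or 95. Obese mouse 22, which had no weight-loss diet, also lay below every measured Control mouse at the named losses other than Agap2. It had 43.9% at Cldn15, 42.7% at Gm11523 and 57.8% at Amotl2, and 50.1% at Agap2. At the named gains it lay within the Control range, except at Gm10392 (58.1%) and Rhbdf2 (64.9%), where it lay above. Part of these losses was thus present in an obese mouse without weight loss, though this is 1 library.

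The promoter CpGs of Arhgap30 lie on chromosome 1 between 171389568 and 171389599, those of Dok3 on chromosome 13 between 55528463 and 55528537, those of Cldn15 on chromosome 5 between 136967847 and 136968030 and those of Agap2 on chromosome 10 between 127079354 and 127080701. Their median average coverage was 109, 65.7, 13.8 and 159 reads. Among single CpGs, 48281 of 129215 were called in MCR against Control, 42412 lower and 5869 higher. The CpGs with the largest gains lay in the body of Cd276, an immune checkpoint ligand (chromosome 9, position 58537353, 63.6 points, SE 8.96, adjusted p = 0.000721), and of Thy1, a surface glycoprotein of T cells and fibroblasts (chromosome 9, position 44047248, 61.4 points, SE 12.6, adjusted p = 0.00253). The CpGs with the largest losses lay in Lgmn, which encodes the protease legumain (chromosome 12, position 102416642, -68.2 points, SE 12, adjusted p = 0.00121), and in Gm32352 (chromosome 8, position 119661271, -66.5 points, SE 12, adjusted p = 0.00122). Called losses made up 41.9% of shelf CpGs, 36.6% of open sea CpGs, 32.5% of shore CpGs and 21% of island CpGs. By Control level, the median difference was -0.0789 points at CpGs under 10%, -19.6 points at CpGs of 50% to 70% and -7.56 points at CpGs over 90%.

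**Figure D2:**
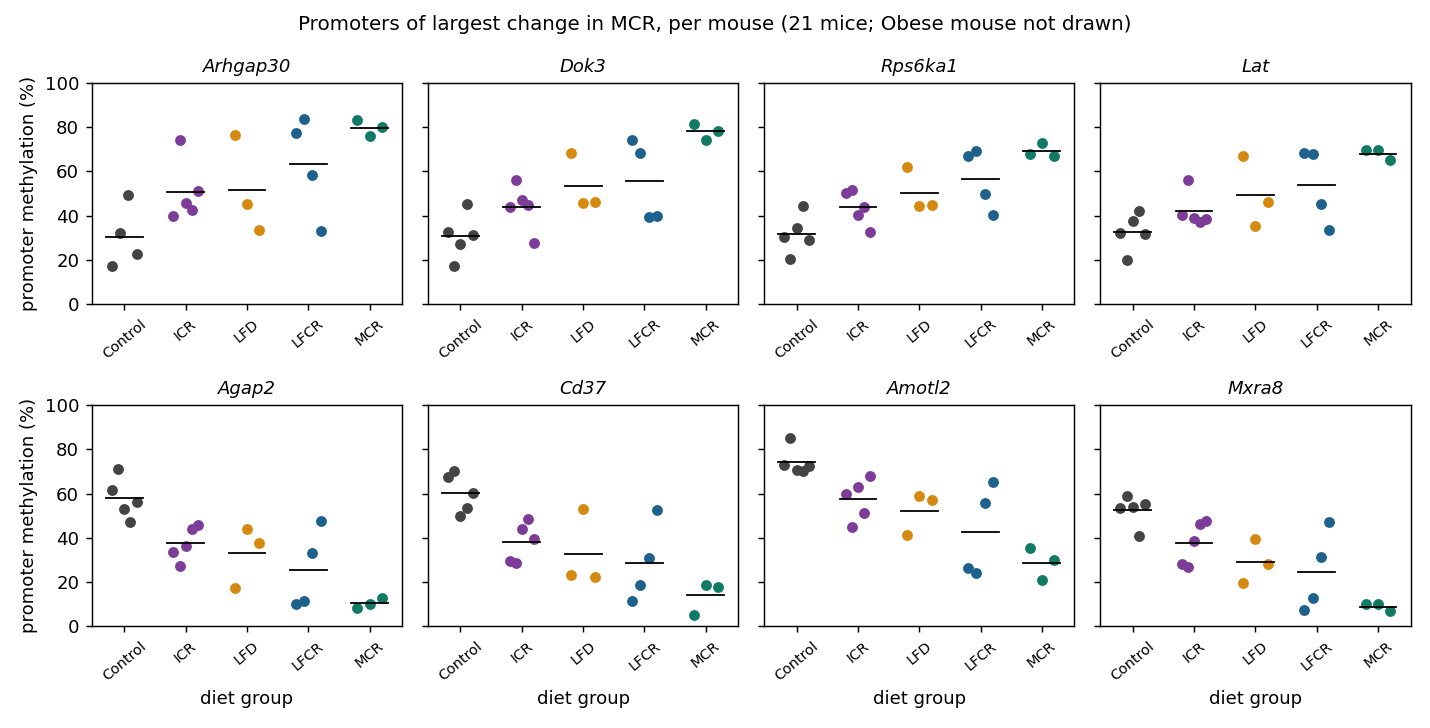
Promoter methylation (percent) per mouse at 8 promoters in Control, ICR, LFD, LFCR and MCR, with 1 point per mouse and a line at each group mean. Arhgap30 had a mean of 30.2% in Control and 79.7% in MCR, and Agap2 57.9% and 10.5%.

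Gene lists fixed before the data were examined held losses in MCR, where 1207 of all 2792 promoters fell. In the test against all other promoters, given below, no list differed. Of 30 Hox cluster promoters, which pattern the body axis, 15 fell and 3 rose over all genes tested, as did 15 and 3 adjusted over the list alone; Hoxa5 fell by 36.6 points (SE 6.67), Hoxa3 by 33.3 (SE 6.19) and Hoxb3 by 26.0 (SE 4.68). Of 9 luminal epithelial promoters 6 fell and none rose over all genes tested, and 7 fell and 1 rose adjusted over the list alone, among them the keratin gene Krt7 (-30.4 points, SE 4.97) and the claudin gene Cldn4 (-18.7 points, SE 4.25). Of 9 insulin, IGF and mTOR signalling promoters 5 fell and 1 rose under both adjustments. Here Pik3cd, a phosphoinositide kinase subunit, fell by 24.1 points (SE 4.15), the kinase gene Akt1 by 17.0 (SE 3.95) and Igfbp6, an IGF-binding protein, by 14.3 (SE 3.05). All 3 inflammation promoters measured fell under both adjustments, with Socs3, a suppressor of cytokine signalling, down from 23.1% to 6.98% and Irf7, an interferon regulatory factor, down from 60.5% to 51.7%. Among 6 thermogenic fat promoters 3 fell under both adjustments, with Cpt1b, the carnitine palmitoyltransferase of muscle and brown fat, down from 72.4% to 35.6%. Dnmt3a, a de novo DNA methyltransferase, fell from 29.2% to 12.5% at its promoter CpGs and Tet3, a DNA demethylase, from 44.0% to 38.7%, so 2 of 3 DNA methylation machinery promoters fell under both adjustments. The 7 CpGs of Dnmt3a lay between positions 3806533 and 3891810 of chromosome 12. Those of Tet3 lay between 83404496 and 83456953 of chromosome 6, so neither value describes a single site. Of 3 lipid synthesis promoters 2 fell under both adjustments, with Acacb, an acetyl-CoA carboxylase, down by 19.7 points (SE 3.89).

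The remaining lists also held losses, where 1207 of all 2792 promoters fell. Of 12 imprinted gene promoters 6 fell and none rose under both adjustments, with H19 down from 79.1% to 56.6% and Gnas down from 45.9% to 38.1%. Of 53 promoters of developmental transcription factors, 13 fell and 3 rose over all genes tested, and 12 and 3 adjusted over the list alone, with Foxf1 up by 11.6 points (SE 2.08) and Barhl1 down by 3.81 points (SE 0.761). Of 7 endothelial promoters 2 fell and 1 rose under both adjustments, with the nitric oxide synthase gene Nos3 down by 16.6 points (SE 3.07) and the endoglin gene Eng up by 13.1 points (SE 4.40), a call lost without Control mouse 2 or MCR mouse 85 or 95. Of 5 skeletal muscle promoters 4 fell and 1 rose under both adjustments, with the creatine kinase gene Ckm at -8.13 points (SE 1.66) and the myogenin gene Myog up by 17.2 points (SE 3.70). In each of the epithelial-mesenchymal transition, tumour suppressor, fibroblast and hormone receptor lists none rose, and 4 of 9, 3 of 5, 2 of 4 and 2 of 4 members fell. In the lymphocyte list 2 of 4 fell and none rose over all genes tested, and 1 rose adjusted over the list alone, with the T cell kinase gene Zap70 down by 21.5 points (SE 6.14), a call lost without MCR mouse 95. None of the 3 adipocyte and 4 basal epithelial promoters changed. In the competitive test against all other promoters (limma cameraPR), no list differed in MCR, with a smallest adjusted p of 0.577, or of 0.999 with an estimated correlation, and 2 of 18 lists had an unadjusted p under 0.05. In the test of each list by itself (limma fry), every list except the adipocyte and basal epithelial ones fell in MCR, with adjusted p from 0.00081 for imprinted genes to 0.0271 for lymphocyte genes, so the lists shared in the general loss. The macrophage and circadian lists had fewer than 3 measured promoters and were not tested. The promoters of Akt1, Socs3 and Dnmt3a turned to differences of 1.21, 0.189 and 0.0994 points when the 1st exon was left out. Their losses thus lay in CpGs annotated to a 1st exon.

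The LFCR pads showed losses and gains at several of the promoters named for MCR, and mice 63 and 67 carried them. In LFCR against Control, 697 promoters were lower and 58 higher. Arhgap30 was higher by 32.9 points (SE 11.3, adjusted p = 0.0443) and Dok3 by 24.8 points (SE 7.80, adjusted p = 0.0311), and Gm12977, Rps6ka1, Tm6sf1, Gm10392, 5830432E09Rik, Lat, Tecr and Rasgrp4 by 19.1 to 27.3 points. Cldn15 fell by 40.3 points (SE 8.70, adjusted p = 0.0159), Agap2 by 32.3 points (SE 7.36, adjusted p = 0.0146) and Cd37 by 31.8 points (SE 8, adjusted p = 0.0165). Tnk2os, Gm11523, Amotl2, Gm15684, 2810433D01Rik and the pair Mex3a and Mir1905, which share their CpGs, fell by 30.5 to 31.7 points. Of the fixed lists, 14 of 30 Hox promoters fell and 1 rose (16 and 2 adjusted over the list alone), Socs3 fell by 9.58 points (SE 1.91) and Cpt1b by 23.3 points (SE 4.69). No list differed from other promoters (cameraPR, smallest adjusted p = 0.577; 0 of 18 lists at an unadjusted p under 0.05). Over CpGs, 15582 were lower and 1912 higher, with the largest gains in 4930519G04Rik (chromosome 5, position 114865071, 47.3 points) and Zfhx3 (chromosome 8, position 108887401, 46.7 points) and the largest losses in Serpina3m (chromosome 12, position 104351358, -59.0 points) and Csnk1e (chromosome 15, position 79436565, -54.7 points). Without LFCR mouse 63 or 67 the calls fell to 12 or 23 CpGs and to 0 promoters for each; without LFCR mouse 72 they rose to 32581 CpGs and 1068 promoters. Without Control mouse 2 they fell to 1079 CpGs and 220 promoters, without Control mouse 13 to 9111 CpGs and 488 promoters, and without Control mouse 1 to 8066 CpGs.

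LFD and ICR pads had no called promoter or CpG against Control, and in LFD a single mouse lay near the MCR mice. LFD mouse 42 had a mean methylation of 48.3%, with Arhgap30 at 76.2% and Agap2 at 17.3%, where LFD mice 47 and 48 had means of 54.6% and 52.5%, Arhgap30 at 45.1% and 33.7% and Agap2 at 43.8% and 38.0%. The mean was 46.5% and 47.1% in LFCR mice 63 and 67 and 46.5% to 47.2% in the MCR mice, so the low state was not limited to the MCR diet. Across 2792 promoters, the differences from Control in LFCR, LFD and ICR correlated with those in MCR at Pearson r of 0.945, 0.903 and 0.877, where the shared Control mice alone gave 0.405, 0.374 and 0.434 in simulation. The simulation drew each promoter independently, so it left out shifts of a mouse that many promoters share. With the Control mice split between the 2 differences the mean r was 0.848, 0.784 and 0.712. Over the splits it ranged from 0.733 to 0.882 in LFCR, 0.635 to 0.837 in LFD and 0.455 to 0.822 in ICR. These are correlations across genes, which are not independent replicates. Of 129215 CpGs and 2792 promoters, limma called 0 and 0 in LFD and 0 and 0 in ICR, with 24372 CpGs and 640 promoters at an unadjusted p under 0.05 in LFD and 16527 and 440 in ICR. The promoters of smallest p in LFD were Ascl5 (-5.50 points), Socs3 (-10.1 points) and Mepce (-3.07 points), each with an adjusted p of 0.0961. In ICR they were Tbc1d17 (3.34 points), Iqcd (6.37 points) and Socs3 (-8.09 points), each with an adjusted p of 0.211. Left-out mice gave up to 32 CpGs in LFD and 2 in ICR. No fixed list differed from other promoters in LFD or ICR (cameraPR, smallest adjusted p of 0.107 and 0.577), with 1 and 0 of 18 lists at an unadjusted p under 0.05.

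Obese pads against Control ask what obesity and the high-fat diet change together, as the Control mice ate another diet. On all 25 libraries, 1320 of 2055 promoters were higher in Obese and 4 lower, and 18898 of 76974 CpGs were higher and 649 lower. Gains were most frequent in CpG islands, where 56.3% of CpGs were called higher, against 32.4% in shores, 10.9% in shelves and 7.41% in open sea. Agpat1, an enzyme of phospholipid synthesis, had 55.9% ± 37.3 (SD, n = 4) in Obese and 0.316% ± 0.374 (SD, n = 5) in Control, a difference of 55.6 points (SE 13.2, adjusted p = 0.00177). Dab2ip, Ldb1, Csnk2b, Pdgfa, Mospd3, Dpf1, C230034O21Rik, Vars and Gemin7 were higher by 50 to 55.1 points, and Mfsd6l, Gm9867 and the pair Gm37564 and Stag2, which share their CpGs, differed by -11.8, -10.5 and -8.37 points. These calls of lower promoters were lost in 6, 4 and 6 of the 9 fits that leave out a single mouse, and Gm9867 was at -4.65 points without Obese mouse 40. At the CpG level the extremes lay in Zfp777 (chromosome 6, position 48047462, 97.2 points) and at chromosome 19, position 23142496, with no gene named (92.2 points), and in Zfp282 (chromosome 6, position 47877896, -70.0 points) and Htr7 (chromosome 19, position 36057392, -61.5 points). The promoter gains were carried by Obese mice 27, 28 and 40. Without the 4 libraries, which leaves Obese mouse 22 alone and takes its spread from the other groups, 9 CpGs were higher and 20 lower and limma called 0 promoters. Mean methylation over 53982 CpGs was 60.2% ± 7.60 (SD, n = 4) in Obese and 51.0% ± 1.46 (SD, n = 5) in Control, a difference of 9.22 points (exact permutation p = 0.0397, adjusted p = 0.0694 over 7 comparisons). That difference was -1.60 points without the 4 libraries. In the authors' table the obese value equals Obese mouse 22 alone, so its contrast of obese with control does not cover the same mice. The authors' own table for this contrast gives 15 CpGs with a q-value under 0.05, 4 higher and 11 lower, and 5.34% of its 53267 tested CpGs have a p-value under 0.05.

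Each weight-loss diet against Obese asks whether the diet undoes the obese state, and these comparisons held mainly the gap between the 4 libraries and the rest. On 25 libraries LFCR, MCR and ICR were lower than Obese at 1652, 1771 and 1449 promoters and higher at 4, 17 and 0. Among the largest losses were promoters raised in the 4 libraries. Agpat1 fell by 55.9 points in LFCR, 55.9 in MCR and 55.7 in ICR, and Ldb1 by 54.7, 54.6 and 54.9. Dab2ip fell by 55.3 in LFCR and ICR, and Csnk2b by 54.5 in MCR. Against this trend, Gm12977, Dok3 and Rps6ka1 were higher in MCR than in Obese by 33.5, 31.6 and 25.8 points, and Gm12977 and the pair Gm14820 and Suv39h1, a histone methyltransferase gene, in LFCR by 19.4 and 16.0 points. In LFCR the call of Gm12977 was lost in 5 of 8 fits that leave out a single mouse, with values of 14.8 to 30.1 points, and that of the pair without LFCR mouse 67. LFD was lower at 946 promoters, led by Dab2ip (-43.4 points), Dpf1 (-38.4 points) and Pitpna (-38.2 points), and higher at the pair Cdkn1c and Gm44732 (10.2 points) and at Ppp1r3f (8.55 points). The 5 CpGs called in LFD were all lower: chromosome 19, position 23142496 (-80.8 points), Mybph (chromosome 1, position 134196014, -65.7 points), Gm11755 (chromosome 11, position 119126540, -62.6 points), chromosome 12, position 19607219 (-40.9 points) and Pmepa1 (chromosome 2, position 173232572, -26.2 points). The other 3 diets had 26730, 39074 and 21203 called CpGs, with the largest gain at Zfp282 and the largest loss at Zfp777 in each of the 3. The Zfp282 CpG does not follow the gap of the 4 libraries: it had 3.31% ± 3.92 (SD, n = 4) over all Obese mice, Obese mouse 22 included, though it was not called in any of the 3 without the 4 libraries. Without the 4 libraries LFD, LFCR, MCR and ICR against Obese mouse 22 had 16, 23, 105 and 23 called CpGs and 1 called promoter each. LFD calls moved with single libraries, to 23851 CpGs and 1534 promoters without LFD mouse 46 and to 21576 and 1441 without Obese mouse 22; without any 1 of the other 6 mice they were 1 to 3 CpGs and 0 promoters.

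The calorie-restricted mice, LFCR, MCR and ICR together, were compared with Obese and with the unrestricted LFD mice, the contrast named in the title of the study. Against Obese, 1693 promoters were lower and 2 higher, led by Agpat1 (-55.8 points), Dab2ip (-55.0 points) and Ldb1 (-54.8 points), with Gm14820 and Suv39h1 higher by 12.3 points, a call lost without Obese mouse 27. Mean methylation was 45.8% ± 3.21 (SD, n = 12) against 60.2% ± 7.60 (SD, n = 4), a difference of -14.5 points (exact permutation p = 0.0011, adjusted p = 0.00769), with 11 of 12 mice below every Obese mouse. It was -4.03 points against Obese mouse 22 alone, and 42 CpGs and 1 promoter were called, in place of 29959 CpGs. Against LFD, limma called 0 of 76974 CpGs and 0 of 2055 promoters, with 4823 CpGs and 99 promoters at an unadjusted p under 0.05. The promoters of smallest p were Mrps10 (-17.0 points), Nptx2 (-8.80 points) and Med25 (-12.2 points), each with an adjusted p of 0.217. Mean methylation differed by -5.64 points (exact permutation p = 0.0736, adjusted p = 0.0859), and by -1.29 points (exact permutation p = 0.563) over the 95331 CpGs measured in all 21 libraries outside the 4. In the single diets against Obese, the mean difference was -8.81 points in LFD, -14.9 in LFCR, -17.9 in MCR and -12.0 in ICR, with adjusted p of 0.171, 0.0667, 0.08 and 0.0556 (exact permutation tests). No fixed list differed from other promoters in any of the 7 comparisons on 25 libraries (cameraPR, smallest adjusted p = 0.053, with 1 to 3 of 15 lists at an unadjusted p under 0.05; smallest adjusted p = 0.994 with an estimated correlation).

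A score placed each mouse between the Control mean (0) and the Obese mean (1) over 1000 CpGs chosen in mice other than the one scored. Obese mice 27, 28 and 40 scored 1.16, 1.04 and 1.20 and LFD mouse 46 scored 1.16, while Obese mouse 22 scored 0.00352 and the other 20 mice 0.0113 to 0.112. None of 9 exact permutation tests between groups passed, with a smallest adjusted p of 0.274. Across 76974 CpGs the change from Control to Obese and the change from Obese to each diet correlated at Pearson r of -0.877 in LFD, -0.858 in LFCR, -0.704 in MCR and -0.942 in ICR. The Obese mice shared by both differences gave -0.528, -0.527, -0.488 and -0.555 in simulation, and with these mice split between the differences r was -0.564, -0.648, -0.510 and -0.738. The covariance was -204, -274, -238 and -304 squared points, against a simulated -30.7, -30.6, -30.6 and -30.6. The simulation gave every group the same spread at each CpG, while Obese mice 27, 28 and 40 lay far from Obese mouse 22. Each part of a split held at least 1 of Obese mice 27, 28 and 40. Neither can therefore tell a reversal by diet from the gap of these libraries. These are correlations across CpGs, which are not independent replicates.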

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

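The tests of the 4 libraries and all counts of splits were chosen only after the results were seen. Of 23 groups of 4 or 5 mice searched for a mouse far from its group, 5 held one, where the critical values of the Dixon test are set for about 1 group in 20 by chance. The groups reuse the same mice over several measures, and all 5 cases are Obese mouse 22 or LFD mouse 46, so they are not independent. LFD mouse 46 had a mean of 48.7% over CpG islands where the other LFD mice had 16.8% to 19.2%, and it scored 1.16 between Control and Obese where the others scored 0.0603 to 0.0694. Obese mouse 22 had a mean of 19.3% over CpG islands where the other Obese mice had 46.5% to 49.2%, and it scored 0.00352 where the others scored 1.04 to 1.20. Obese mouse 22 also had values at 282504 CpGs where the other Obese mice had 139399 to 158182.

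These mice mark 1 pattern, in which Obese mice 27, 28 and 40 and LFD mouse 46 carry near 50% methylation at CpGs that all other libraries have unmethylated. DNA of tumour or other cells in the pad would leave housekeeping promoters, which every cell type keeps open, unmethylated, but the lowest median over these promoters among the 4 libraries was 49.4%. Obesity itself would raise Obese mouse 22 too, which was at 1.66% at these CpGs. Unconverted reads spread evenly over the genome would raise CpGs of 10% to 30% nearly as much as CpGs under 5%, but the gap there was 0.0801 of that at CpGs under 5%. None of the 3 explanations accounts for the pattern, and a cause in the making or the merging of these 4 columns was not tested.

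Other splits of the same mice into groups of the same sizes were counted for each comparison. In Obese against Control 3 of 100 splits gave as many called CpGs (19547, highest other 20190) and 4 of 100 as many promoters (1324, highest other 1383). Against Obese 1 split, the real one, gave as many: 26730 CpGs (highest other 26357) and 1656 promoters (1638) in LFCR, 39074 (32824) and 1788 (1725) in MCR, and 21203 (21064) and 1449 (1424) in ICR. For the calorie-restricted mice against Obese 1 of 100 splits gave 29959 CpGs (highest other 9450) and 1695 promoters (highest other 302). Obese mice 27, 28 and 40 carry these 5 comparisons, in which at most 1 promoter is called without the 4 libraries. The counts therefore do not exclude a chance placing of these libraries in the Obese group. In LFD against Obese 15 of 35 splits gave at least the 5 real CpGs, up to 28498, and 5 of 35 the 949 real promoters, up to 1656, so chance cannot be excluded. For the calorie-restricted mice against LFD the real count was 0, which all 100 splits meet by definition, with up to 10051 CpGs and 96 promoters in other splits. In both, splits that call many more than the real one point to a structure of the mice. In LFD against Obese, leaving out LFD mouse 46 raised the calls to 23851 CpGs and 1534 promoters. Leaving out Obese mouse 22 raised them to a similar extent, and no other left-out mouse did. For the calorie-restricted mice against LFD every left-out mouse gave 0 calls, and the structure was not traced to single libraries. On the 21 libraries MCR against Control stood alone among 56 splits, with 1 as large (48281 CpGs, highest other 418, and 1326 promoters, highest other 294). This is the smallest share that 56 splits of these 8 mice can give. The count was also chosen after the results were seen, so chance is not taken as excluded. LFCR mice 63 and 67 and LFD mouse 42 have means near those of MCR, so the count does not tie the low state to the MCR diet. In LFCR against Control 2 of 100 splits were as large for CpGs (17494, highest other 22934) and 2 of 100 for promoters (755, highest other 927). Another split gave more calls and LFCR mice 63 and 67 carry the real ones, so chance is not taken as excluded. LFD and ICR against Control had 0 calls, met by 56 of 56 and 100 of 100 splits (highest other 45 CpGs and 3 promoters in LFD, 6 CpGs and 1 promoter in ICR).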

How the results depend on the processing

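The setting without the 4 libraries, the promoters without the 1st exon, the arcsine square root scale and the lists over all CpGs of a gene were chosen only after the results were seen. The loss of methylation in MCR against Control held in the counts of calls: without any single mouse 37676 to 49328 CpGs and 1104 to 1332 promoters were called. Its difference in mean methylation stayed at -9.83 to -8.78 points, but the exact permutation test lost its call in 4 of 8 fits that leave out a mouse. The other comparisons depended on the 4 libraries or on single mice. A coverage minimum of 5 reads removed no tested CpG and so tested nothing. The promoter window by distance from the start and the methylated share of all reads were not run, since the table has no start sites or counts.

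Without the 4 libraries the called CpGs were 29 in Obese against Control, 16, 23, 105 and 23 in LFD, LFCR, MCR and ICR against Obese and 42 in the calorie-restricted mice against Obese. In Obese against Control, LFD, ICR and the calorie-restricted mice against Obese most of them had the opposite sign. The called promoters were 0 in Obese against Control and 1 in each of the other 5. Mean methylation in Obese minus Control turned to -1.60 points, and against Obese it was -4.50 in LFCR, -7.71 in MCR, -1.44 in ICR and -4.03 in the calorie-restricted mice. The 4 libraries hold 3 of 4 Obese mice, so this setting leaves 1 Obese mouse and most gains go by construction. Of the promoters named in Obese against Control, Agpat1 turned to -0.316 points, Dab2ip to -0.775, Ldb1 to -0.311, Csnk2b to -0.313, Pdgfa to -0.606, C230034O21Rik to -0.354 and Gemin7 to -1.44, and Gm37564 and Stag2 to 2.90 and 2.90. Against Obese, Ldb1 turned to 0.385 in LFCR, 0.431 in MCR, 0.113 in ICR and 0.283 in the calorie-restricted mice. Csnk2b turned to 0.252 in MCR, Agpat1 to 0.227 in ICR and 0.0944 in the calorie-restricted mice, and Dab2ip to 0.133 in ICR.

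With at least 10 CpGs per promoter, where 396 or 666 promoters were tested, the calls were 161 in Obese against Control, 0, 303, 336 and 218 in LFD, LFCR, MCR and ICR against Obese, 315 in the calorie-restricted mice against Obese, and 5, 395 and 508 in LFD, LFCR and MCR against Control. Without the 1st exon, where 493 or 758 promoters were tested, they were 311 in Obese against Control, 219, 393, 429 and 328 in LFD, LFCR, MCR and ICR against Obese, 402 in the calorie-restricted mice against Obese, and 212 and 340 in LFCR and MCR against Control. Fewer promoters were tested in both settings, but the share called moved in both directions, and the cause was not tested. In MCR against Control, Akt1 turned to 1.21 points, Socs3 to 0.189 and Dnmt3a to 0.0994 without the 1st exon. In LFD against Obese a coverage minimum of 20 reads gave 3 CpGs, and the arcsine scale gave 86 CpGs and 0 promoters; the cause was not tested.

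The lists over all CpGs of a gene gave 2 called lists in Obese against Control, 2 in LFD against Obese, 2 in ICR against Obese, 2 in the calorie-restricted mice against Obese, 2 in MCR against Control, and 1 each in the calorie-restricted mice against LFD and in LFD, LFCR and ICR against Control; none is called with an estimated correlation. The score of LFCR minus Control turned to -0.00161 with more CpGs in the score, -0.0336 as a median position and -0.00889 with 200 promoters. That of MCR minus Control turned to -0.0238 as a median position and -0.00424 with 200 promoters, and that of ICR minus Control to 0.00645 with fewer CpGs in the score; no value of these was called and the cause was not tested. With the Obese mice split 2 and 2, the correlation of the obese change with the diet change was -0.564 in LFD, -0.648 in LFCR, -0.510 in MCR and -0.738 in ICR. This split removes the shared mice and also leaves 2 Obese mice per difference, and the cause was not tested.

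Leaving out each mouse in turn gave these ranges. LFD against Obese had 1 CpG without Obese mouse 27 to 23851 without LFD mouse 46, and 0 promoters to 1534 for the same mice. LFD against Control had 0 to 32 CpGs (without LFD mouse 47) and 0 to 2 promoters (without Control mouse 10). LFCR against Control had 12 CpGs without LFCR mouse 63 to 32581 without LFCR mouse 72, and 0 to 1068 promoters. ICR against Control had 0 to 2 CpGs (without Control mouse 5) and 0 to 1 promoter (without Control mouse 10). Mean methylation in Obese minus Control was 7.34 points (without Obese mouse 28) to 12.8 (without Obese mouse 22), and in ICR minus Obese -15.6 (without Obese mouse 22) to -10.1 (without Obese mouse 28). Minus Control it was -5.73 to -2.60 in LFD (without LFD mouse 47 and 42), -7.58 to -4.93 in LFCR (without LFCR mouse 72 and 63), -9.83 to -8.78 in MCR (without Control mouse 10 and 2) and -3.56 to -2.47 in ICR (without Control mouse 10 and ICR mouse 103). With 1 mouse fewer an exact test has fewer splits, which raises its smallest possible p by construction. Without Control mouse 2 and without Obese mouse 28 the score minus Control was -0.0466 and 0.0971 in LFCR, -0.0206 and 0.202 in MCR and -0.0378 and 0.0371 in ICR. The score of the calorie-restricted mice minus LFD was -0.359 without LFD mouse 47 and 0.00650 without LFD mouse 46. The 140 promoters and CpGs named in the text had 1554 values over all alternatives, of which 1534 had the direction of the printed value, 20 had the opposite one and 215 lost the call. For these results the cause was not tested.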

Other observations

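The tests of an even loss alone and of the cell type lists, and the tests over all CpGs of a gene, were chosen only after the results they bear on were seen. Genes that control development had smaller losses than other genes when all CpGs assigned to a gene were averaged, which is not called with an estimated correlation and was not tested against genes of the same starting level. The loss depends on that level, with a median of -0.0789 points at CpGs under 10% in Control and -19.6 points at CpGs of 50% to 70%, so the difference between lists is left open. In MCR against Control the 67 developmental transcription factor genes had a median difference of -1.31 points where other genes had -6.74 (cameraPR adjusted p = 7.18e-06, adjusted p = 0.331 with an estimated correlation), with 12 called higher and 22 lower, or 12 and 21 adjusted over the list alone. The 37 Hox genes had a median of -2.82 points, against -6.71 in other genes (adjusted p = 0.0414, adjusted p = 0.475 with an estimated correlation). In LFD, LFCR and ICR against Control the medians of the developmental list were -0.0809, -1.17 and -0.643 points where other genes had -3.03, -4.35 and -2.11, with adjusted p of 6.10e-06, 0.00112 and 0.0175, or 0.331, 0.475 and 0.654 with an estimated correlation.

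The lower methylation of MCR than of Control mice was weighed against technical causes. A difference that came from low depth would shrink towards 0 at well covered CpGs. The median difference at partly methylated CpGs was -10.6 points in the third of lowest average coverage and -11.4 points in the third of highest. This coverage is an average over libraries and the depth of each library is unknown, so a difference in depth between libraries is not excluded. An even loss, as bisulfite conversion or calling might give, would lower imprinted promoters of 35% to 65% as much as other promoters of that level, and it did: 5 imprinted promoters had a median of -7.79 points and 603 others -9.22, a ratio of 0.845, as predicted before that value was seen. Such a loss alone would raise no promoter, but 28 of these 608 were called higher beside 391 called lower. Of the 608, 46.1% lay more than 2.5 SE from their median difference. That share cannot decide, since the loss depended on the level of single CpGs and a promoter can mix CpGs of several levels. Both criteria were set after the ratio was known. An even loss therefore stays open as a part of the difference, but not as the whole of it.

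A hypothesis for the gains is fewer leukocytes in the MCR pads, since genes kept unmethylated in leukocytes would then read higher. It arose from higher promoters already named, such as Arhgap30, Dok3, Lat and Inpp5d. These and Cd37, which fell, were left out of a list of 69 leukocyte genes written before the values of its genes were seen. Here and in the random lists a promoter needed a single CpG instead of 3. Of the listed genes, 15 had a promoter value, with a median difference of 0.331 points where random promoter lists of matched level had -4.92, above 99.7% of 10000 such lists. Arhgap45 was higher by 46.6 points (SE 9.42, adjusted p = 0.00223), the exchange factor Vav1 by 24.5 points (SE 4.10, adjusted p = 0.00142) and the actin regulator Coro1a by 24.4 points (SE 4.34, adjusted p = 0.00165), and Sipa1 and Arhgef1 were also called higher. Apobr fell by 38.1 points (SE 9.13, adjusted p = 0.00555), against the hypothesis, as do the leukocyte gene Cd37 and the lymphocyte kinase gene Zap70, and 6 of the 15 were lower and 8 higher. The median above 0 is that of the single gene Ikzf1 (0.331 points, SE 17.5). The list as a whole thus lacked the general loss and did not clearly rise. Its rank among random lists is taken over genes, which are not replicates of the mice. A smaller share of leukocytes stays possible as a cause of part of the gains. A broader test, of 8 cell type lists with 3 to 9 measured members against other promoters, called 0 lists (smallest adjusted p = 0.861), and so few members leave a shift of cell types undecided.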
